A study of Mus musculus with 2 samples.

How the data were processed

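Single-cell 3' RNA libraries of the mouse melanoma lines B16F0 and B16F10 were prepared by the submitters with the 10x Chromium kit of chemistry v2, 1 library per line, per the labels' protocols. Cell Ranger 3.0.0, Seurat 3.0 and the genome build mm10 are named in the submitters' processing notes, with no role or order. The aligner settings and the filters on cells are not given in the sources used here. The authors deposited a table of raw UMI counts for 14959 genes and 4156 cells, per the file headers, and a second table of natural log values. The deposited natural log values equal the natural log of 1 plus the count divided by the cell's total and multiplied by 10000, with a largest absolute difference of 6.22e-15 from the recomputed values, and they served only for that check. Both tables were present a second time as byte for byte copies, which were not used. The authors also deposited a table of classes and scores per cell, per the file headers: the line, clusters, a cycling class, a trajectory state and pseudotime, a Kdm5b class, S and G2/M scores, and a GSVA score for MITF. How these scores and classes were made is not given in the sources used here, except that the cycling class was found to equal a score above 0 for S or for G2/M.

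Cells were assigned to a library by the line named in the deposited cell table. All deposited cells were kept. They held between 3011 and 6996 genes, and their mitochondrial share reached at most 19.9%, so filters on both had evidently been applied before deposit. No doublet caller was run, and the alternative without the 5% of cells with the most UMIs in each library addresses possible doublets. The libraries held 94268486 and 56748682 UMIs, so 3 counts, the limit that a count of 0 allows, correspond to 0.0318 CPM in B16F0 and 0.0529 CPM in B16F10. The same barcode sequence occurred in both libraries 6 times.

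Raw counts were summed over the cells of each library and scaled by the library total to CPM. The log2 ratio B16F10 over B16F0 carries an exact 95% interval from the conditional binomial distribution, and CPM values carry exact Poisson intervals. Shares of cells carry exact Clopper-Pearson intervals. Cells are not replicates, so no test was made, no p-value is given, and genes were counted by a fixed size: at least 2-fold, with at least 20 CPM in the higher library. For each of 36 gene lists the median log2 ratio was taken over members with at least 10 CPM in the higher library, where at least 3 such members existed. It was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. List members were counted as higher or lower at 1.5-fold.

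The design, the gene lists, the thresholds, the rule for naming genes and most alternatives were set before the data were examined. The rule names the 12 genes with the highest and the 12 with the lowest ratio among those with at least 50 CPM in the higher library, leaving out predicted, ribosomal protein and mitochondrially encoded genes. It also names the 3 members with the largest absolute log2 ratio of each list at 20 CPM or more, 17 fixed melanoma and cell state genes, and the 10 genes with the largest Fano factor in each line. Outside this rule, Mc1r, Cd63, Lgals1, Loxl2, Nuak1 and L1cam were named after the values were seen, to show which members moved a list. Comparisons between the authors' classes within a line were added once the deposited classes were seen, and the genes named there have at least 50 CPM in the higher class of each line and are among the 8 at either end by mean log2 ratio, apart from Kdm5b and Mitf, which were chosen by name. Genes that define a class or cluster are not reported as results of it.

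For shares of cells, phase calls, Fano factors and correlations, each cell was thinned without replacement to 23173 UMIs, the 10th percentile of UMIs per cell in B16F10. This left out 388 shallower cells of B16F0 and 158 of B16F10. Phase calls used the scanpy scoring with the S phase and the G2 and M phase lists. Fano factors were taken for genes with a mean of at least 0.1 thinned UMI per cell, and list correlations were compared with 1000 matched random lists. Gene positions came from GENCODE release M21 on GRCm38, where 14751 symbols, 98.6% of them, matched exactly 1 gene.

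Alternatives were TMM factors from edgeR, size factors from DESeq2, a total without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, other sets of cells and other CPM minimums. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, with matplotlib 3.10.9 for the plots. The ratio and list steps were tested on simulated Poisson counts for 14959 genes in libraries of these sizes, of which 4964 had at least 20 CPM. The intervals held 94.9% of the true ratios, all 173 changed genes at 20 CPM or more were found at 2-fold with 0 unchanged genes beside them, and 7 of 100 random lists fell outside the central 95%. The planted folds were 4, 2.5, 0.4 and 0.25, all beyond the 2-fold cut. Spread between cells or cultures beyond counting error was not simulated, so these results check the arithmetic and not the real libraries.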

Results

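Messenger RNA was counted in single cells of 2 mouse melanoma cell lines with a droplet method that tags the 3' end of each transcript and counts molecules by unique molecular identifiers (UMIs). B16F0 is the parental line of the B16 melanoma, and B16F10 is labelled a highly metastatic subclone of it. Each line was represented by 1 library, so no difference below has a replicate check, and every interval covers counting error only. The B16F0 library held 2582 cells and 94268486 UMIs, with a median of 35503.5 UMIs and 5215 genes per cell. The B16F10 library held 1574 cells and 56748682 UMIs, with a median of 34950.5 UMIs and 5385 genes per cell. Mitochondrially encoded transcripts took 5.41% of the UMIs in B16F0 and 6.78% in B16F10, and ribosomal protein transcripts took 28.5% and 26.3%.

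The first comparison asks which transcripts differ between the parental line and the metastatic subclone. Tmsb4x, which encodes an actin monomer-binding peptide, stood at 2.24 CPM (95% Poisson interval 1.95 to 2.56) in B16F0 and at 97.4 CPM (94.8 to 99.98) in B16F10, a log2 ratio of 5.44 (5.24 to 5.65). Ppargc1a, a coactivator that drives mitochondrial biogenesis, stood at 4.78 CPM (4.35 to 5.25) in B16F0 and at 124 CPM in B16F10, a log2 ratio of 4.70 (4.56 to 4.84). Met, the receptor tyrosine kinase for hepatocyte growth factor, went from 13.1 CPM (12.4 to 13.9) to 142 CPM (139 to 146), a log2 ratio of 3.44 (3.35 to 3.53). In the opposite direction, Fam178b stood at 147 CPM (144 to 149) in B16F0 and at 10.9 CPM (10.1 to 11.8) in B16F10, a log2 ratio of -3.75 (-3.86 to -3.63). Mgst1, a microsomal glutathione transferase, stood at 97.1 CPM (95.2 to 99.1) and 13.0 CPM (12.1 to 14.0), a log2 ratio of -2.90 (-3.01 to -2.79).

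On mouse assembly GRCm38, Tmsb4x lies on chromosome X from 167207093 to 167209315, Ppargc1a on chromosome 5 from 51454250 to 51567726, and Met on chromosome 6 from 17463800 to 17573980. Fam178b lies on chromosome 1 from 36562692 to 36683183 and Mgst1 on chromosome 6 from 138140316 to 138156755. All 5 are annotated as protein-coding genes, and the counts are over each whole gene.

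Among the other transcripts higher in B16F10, Lgals3, a galactoside-binding lectin, had 88.8 CPM in B16F0 and 508 CPM in B16F10, a log2 ratio of 2.51. Mcam, a cell adhesion molecule first described in melanoma, had a log2 ratio of 1.67, and Sparc, a matricellular glycoprotein, rose from 336 to 1006 CPM at a log2 ratio of 1.58. The phosphodiesterase gene Pde10a had a log2 ratio of 3.07, the insulin receptor adaptor gene Grb14 of 2.75, and the secreted phospholipase gene Pla2g2e of 2.38. Lhfp followed at 2.32 and the creatine transporter gene Slc6a8 at 1.79, and Fam198b went from 67.0 to 268 CPM.

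The transcripts lower in B16F10 included both prostaglandin D synthases. Ptgds had 1393 CPM in B16F0 and 222 CPM in B16F10, a log2 ratio of -2.65, and Hpgds had 66.6 and 11.1 CPM, a log2 ratio of -2.59. The cystine-glutamate exchanger gene Slc7a11 was at 248 CPM in B16F0 and 60.9 CPM in B16F10, a log2 ratio of -2.02, and the glutathione transferase gene Gstm1 had a log2 ratio of -1.93. The chemokine gene Ccl5 had a log2 ratio of -2.37, the lens filament gene Bfsp2 of -2.17, and the electron carrier gene Cyb5a of -1.94. Ccl5 was seen in only 8.39% of thinned B16F0 cells and 2.82% of thinned B16F10 cells, so its ratio rests on few cells. Rad54l, which acts in recombinational DNA repair, had a log2 ratio of -1.93, the myelin gene Mbp of -1.91 and Fam174b of -1.77.

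**Figure D1:**
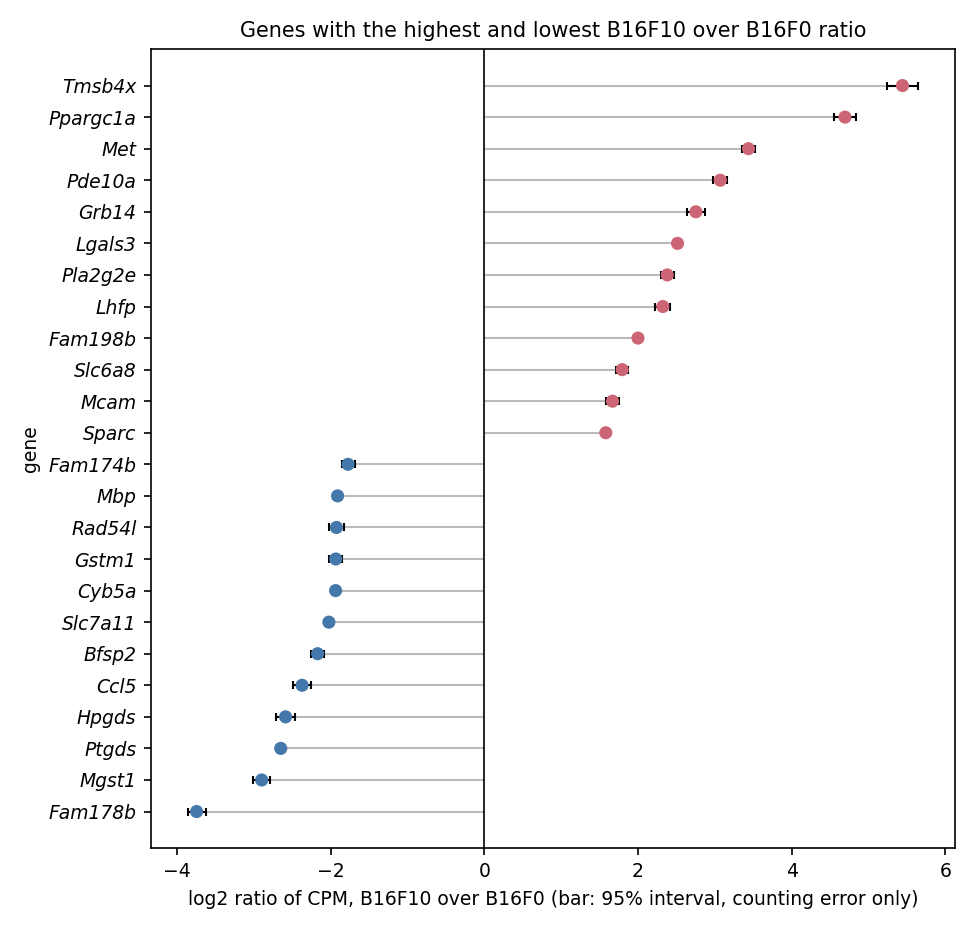
Log2 ratio of CPM, B16F10 over B16F0, for the 12 genes with the highest and the 12 with the lowest ratio among genes with at least 50 CPM in the higher library; points are ratios and bars are 95% intervals for counting error in 1 library per line. The ratios run from 5.44 for Tmsb4x to -3.75 for Fam178b.

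Of 5296 genes with at least 20 CPM in the higher library, 81 were at least 2-fold higher and 85 at least 2-fold lower in B16F10, and 5130 lay within 2-fold. At 4-fold or more, 12 genes were higher and 18 lower. The median gene had a log2 ratio of 0.12, and TMM and median-of-ratios scaling moved that median by -0.11, which gave 55 higher and 110 lower genes under TMM and 54 higher and 112 lower under median-of-ratios. Ratios near 0.12 are therefore ratios of the typical gene. Genes with near-identical copies, such as Ftl1, Gapdh and Ppia, are uncertain, because the handling of reads shared between copies is not given in the sources used here.

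The shares of cells with at least 1 UMI followed the same genes. After each cell was thinned to 23173 UMIs, Met was seen in 19.6% of B16F0 cells (18.0 to 21.4) and 82.6% of B16F10 cells (80.6 to 84.6), against 26.2% and 88.5% without thinning. Ppargc1a was seen in 8.93% (7.77 to 10.2) and 74.4% (72.1 to 76.7) of thinned cells, against 12.2% and 82.8% without thinning. Tmsb4x was seen in 2.78% and 62.6% of thinned cells (3.29% and 69.9% without thinning), Fam178b in 85.8% and 18.4% (90.4% and 24.5%), and Tyr in 52.9% and 25.6% (57.4% and 29.9%). Neither culture holds a cell type that should lack these genes, so the share that free RNA alone would give was not measured.

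The next comparison asks which groups of genes move together. The pigment list went both ways: of 17 measured members, 3 were at least 1.5-fold higher in B16F10, 5 at least 1.5-fold lower and 9 between. The higher members were Met, the receptor gene given above, Mc1r at a log2 ratio of 0.73, and Tyrp1. The lower members were Tyr, Trpm1, Cd63 at -1.22, Pmel and Mlana. Tyr, the rate-limiting enzyme of melanin synthesis, fell from 64.3 to 19.2 CPM, a log2 ratio of -1.74 (-1.84 to -1.65), and the channel gene Trpm1 had a log2 ratio of -1.22. The melanosome structural gene Pmel and the melanosomal antigen gene Mlana had log2 ratios of -0.76 and -0.77. The melanin synthesis genes Tyrp1 and Dct were on the other side, at 0.69 and 0.34. Mitf, the master regulator of the melanocyte lineage, was at 90.5 CPM in B16F0 and 164 CPM in B16F10, a log2 ratio of 0.86 (0.82 to 0.90), and its partner regulator gene Sox10 had a log2 ratio of 0.40.

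The list median of the pigment genes, 0.17, lay inside the central 95% of matched random lists (-0.20 to 0.24). The lineage regulators had a median of 0.22, also inside their random range (-0.17 to 0.36), with 2 of 10 members higher and 3 lower. Erbb3 was among the lower members, at a log2 ratio of -1.09. The authors' deposited per-cell score for MITF, whose gene set is not given in the sources used here, had a median of 0.057 (SD over cells 0.316) in B16F0 and -0.165 (SD 0.260) in B16F10.

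Interferon-stimulated genes were lower in B16F10, as were some antigen presentation genes. Of 10 measured interferon response genes, 9 were at least 1.5-fold lower and none was 1.5-fold higher, with a list median of -1.13 against a random range of -0.16 to 0.38. The ubiquitin-like modifier gene Isg15 had a log2 ratio of -2.03 (-2.19 to -1.88), Lgals3bp of -1.52 and the tetherin gene Bst2 of -1.27. Isg15 was seen in 17.9% of thinned B16F0 cells and 5.51% of thinned B16F10 cells, so its ratio rests on a minority of cells. Of 8 measured members of the MHC class I list, 4 were at least 1.5-fold lower and none higher, with a median of -0.59 (random range -0.31 to 0.38), and 4 lay between. B2m, the invariant chain of MHC class I, had 436 CPM in B16F0 and 188 CPM in B16F10, a log2 ratio of -1.22, and the heavy chain genes H2-D1 and H2-K1 had log2 ratios of -0.89 and -0.99. The immune checkpoint ligand gene Cd274 was rare in both lines, at 1.85 and 1.13 CPM (log2 ratio -0.71, -1.15 to -0.29). Limited to members with at least 100 CPM, the MHC class I list kept 4 members and a median of -0.11, inside its random range.

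The lysosome list and the oxidative stress and iron list also had medians below their random ranges. Of 23 measured lysosome and autophagy genes, 9 were at least 1.5-fold lower and none higher, with a median of -0.53 (random range -0.12 to 0.26). The progranulin gene Grn had a log2 ratio of -1.45, the autophagy receptor gene Sqstm1 of -1.12 and the protease gene Ctsl of -0.86. In the oxidative stress and iron list, 7 of 18 members were at least 1.5-fold lower and 1 higher, with a median of -0.20 (random range -0.15 to 0.26). Slc7a11, given above, led this list, followed by the heme oxygenase gene Hmox1 at -1.45 and the peroxiredoxin gene Prdx1 at -0.94. The ferritin light chain gene Ftl1 was on the other side, at 0.46. Limited to members with at least 100 CPM, the oxidative stress and iron median was -0.11, inside its random range.

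Most measured members of the mesenchymal and glycolysis lists were higher in B16F10. In the mesenchymal and invasion list 6 of 11 members were at least 1.5-fold higher and 3 lower, with a median of 0.77 (random range -0.19 to 0.39). Sparc and Mcam led, the fibronectin gene Fn1 had a log2 ratio of 1.08 and the hyaluronan receptor gene Cd44 of 0.89, while the intermediate filament gene Vim had -0.86. S100a4, named here after the values were seen because it changed most in the list, had a log2 ratio of -3.51 and 1.06 CPM in B16F10. The median counts each member alike, and the summed list was lower in B16F10, at 5645 CPM in B16F0 and 4516 CPM in B16F10. Its most abundant member, Lgals1, had 3925 CPM in B16F0 and 2487 CPM in B16F10, a log2 ratio of -0.66. The mesenchymal and invasion median fell inside its random range with no CPM minimum (0.26), at a minimum of 100 CPM (0.12) and with a total without mitochondrial and ribosomal protein genes (0.35). In the extracellular matrix list 3 of 7 members were at least 1.5-fold higher and none lower, with a median of 0.48 (random range -0.24 to 0.45) and Hspg2 and Lamc1 at 0.80 and 0.60. The dedifferentiated or neural crest list had 3 of 6 members higher and 2 lower, with a median of 0.65 (random range -0.24 to 0.50). Of its 18 genes, 10 were in the deposited counts and 6 reached 10 CPM. Loxl2, Tead1 and Nuak1 were higher, at 1.09, 0.87 and 0.75, and Jun had 0.54. Nes and L1cam were lower, at -0.94 and -1.10, so the members did not move as 1 group. The dedifferentiated or neural crest median was 0.40 among cells called neither S nor G2/M, inside its random range.

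Of 16 glycolysis genes, 9 were at least 1.5-fold higher in B16F10 and none lower, with a median of 0.62 (random range -0.19 to 0.26). The phosphofructokinase genes Pfkl and Pfkp had log2 ratios of 1.36 and 0.90, and the aldolase gene Aldoa had 0.85. Among 14 hypoxia response genes 5 were higher and none lower, and their median of 0.37 lay just inside its random range (-0.12 to 0.39). The mitophagy receptor gene Bnip3 had a log2 ratio of 1.44, Fam162a of 0.48 and Ndrg1 of -0.45. The 13 mitochondrially encoded transcripts had a median of 0.39 (random range -0.25 to 0.24), with mt-Nd5 at 0.63, mt-Nd2 at 0.48 and mt-Co1 at 0.44. Among cells with at most 8% mitochondrial UMIs the median of the mitochondrially encoded transcripts was 0.17, inside its random range. That cut is made on these same transcripts and leaves out a larger share of B16F10 cells, so it lowers the median whatever the cause. The 39 nuclear-encoded genes of oxidative phosphorylation had a median of -0.13, inside their random range (-0.16 to 0.10), with Atp5b at -0.80 and Sdhb at 0.65.

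The cell cycle lists had medians above their random ranges over all cells. Of 49 G2 and M phase genes, 23 were at least 1.5-fold higher in B16F10, 26 lay between and none was lower, with a median of 0.54 (random range -0.01 to 0.24). The kinetochore motor gene Cenpe and Gas2l3 each had a log2 ratio of 1.09, Kif23 had 1.02, Mki67 had 0.81 and the topoisomerase gene Top2a had 0.67. Of 42 S phase genes, 13 were higher, 29 between and none lower, with a median of 0.31 (random range -0.01 to 0.27), led by the ribonucleotide reductase genes Rrm1 at 1.18 and Rrm2 at 0.96, and by Uhrf1 at 0.92. The S phase median was 0.048 among cells the authors called cycling, inside its random range, and turned to -0.059 among cells called neither S nor G2/M and to -0.027 among non-cycling cells. The G2 and M phase median was 0.17 among cycling cells, also inside its random range. It was 0.34 among non-cycling cells and 0.29 among cells called neither, both above their random ranges. In the MAPK output list 4 of 8 members were higher and none lower, with a median of 0.51 (random range -0.20 to 0.45). The cyclin D1 gene Ccnd1 went from 56.4 to 143 CPM, a log2 ratio of 1.34, and the phosphatase gene Dusp4 had 0.90. The MAPK output median fell inside its random range with the mean of per-cell CPM (0.33), among cells called neither (0.44), and among cycling (0.39) and non-cycling cells (0.41). The cell cycle inhibitor gene Cdkn1a was at 334 CPM in B16F0 and 181 CPM in B16F10, a log2 ratio of -0.88.

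**Figure D2:**
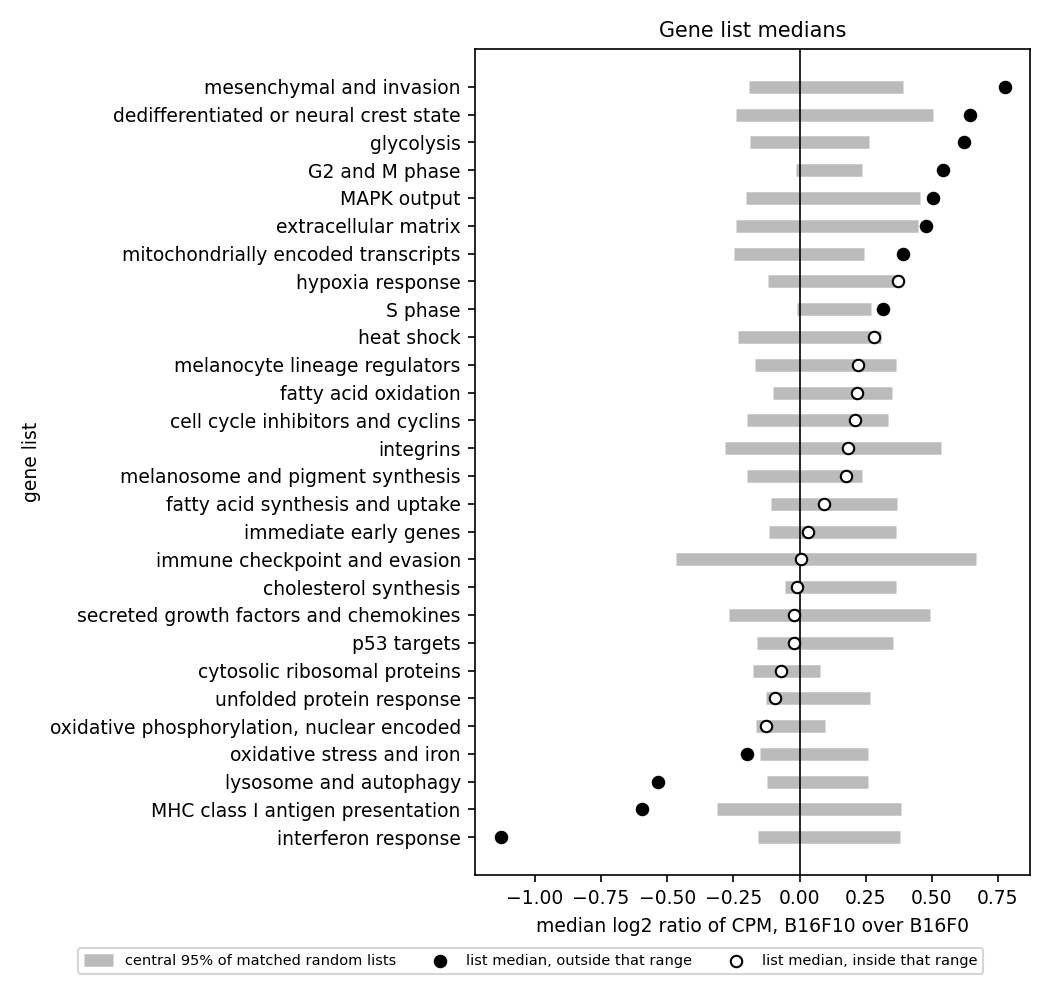
Median log2 ratio of CPM, B16F10 over B16F0, for the 28 gene lists with enough measured members; points are list medians and grey bars the central 95% of 10000 random lists matched on expression, for 1 library per line. The interferon list lies lowest at -1.13 and the mesenchymal list highest at 0.77, both outside their grey bars.

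The other lists had medians inside their random ranges over all cells. Fatty acid oxidation had a median of 0.22, although it holds Ppargc1a, and integrins had 0.18, heat shock 0.28, and cell cycle inhibitors and cyclins 0.21. The heat shock list holds Hspb1, a small chaperone gene at 24.5 CPM in B16F0 and 0.775 CPM in B16F10, a log2 ratio of -4.98 (-5.45 to -4.55). The unfolded protein response list had a median of -0.09, with the asparagine synthetase gene Asns at -1.30 and Herpud1 at -0.96. Cholesterol synthesis had a median of -0.01, p53 targets -0.02, secreted factors -0.02 and cytosolic ribosomal proteins -0.07. Fatty acid synthesis and uptake had 0.09, immediate early genes 0.03 and immune checkpoint genes 0.01, all below the 0.12 of the typical gene. Heat shock lay above its random range among cells the authors called cycling, at 0.39. Among cells the authors called non-cycling, heat shock turned to -0.30, cholesterol synthesis had -0.36 and p53 targets 0.46, all outside their random ranges, and nuclear oxidative phosphorylation turned to 0.090, above its range. In all, 28 lists had a median, 8 lay above and 4 below their random range.

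Most of the measured markers of other cell types were near absent. Of 10 markers each, the deposited counts held 5 for fibroblasts, 4 for macrophages, 1 for T and NK cells, 2 for keratinocytes and 5 for endothelium. Summed over the markers held, fibroblast markers reached 5.73 CPM in B16F0 and 6.84 CPM in B16F10, and macrophage markers 9.77 and 6.84. The T and NK cell marker had 0.647 and 1.37 CPM, and keratinocyte markers reached 1.36 and 0.758. Endothelial markers summed to 68.6 and 67.1 CPM, of which Egfl7 alone made up 66.2 and 63.0. The 2 measured epithelial adhesion genes, Ctnnb1 and Tjp1, had log2 ratios of 0.72 and 0.59, and the metallothionein genes Mt1 and Mt2 had -0.42 and -0.57. No erythroid marker was analysed here.

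The third comparison sets the phase calls of the cells beside the cell cycle lists. Called from thinned cells, 32.0% of B16F0 cells and 42.4% of B16F10 cells were in S phase, and 25.9% and 38.6% in G2 or M. Cells called neither made up 42.1% of B16F0 (40.0 to 44.2) and 19.0% of B16F10 (17.0 to 21.1). On all counts the shares called neither were 42.4% and 20.6%. The authors' deposited calls put 1411 of 2582 B16F0 cells (54.6%, 52.7 to 56.6) and 1230 of 1574 B16F10 cells (78.1%, 76.0 to 80.2) in the cycling class. That class is a cut on the authors' S and G2/M scores at 0, and 262 B16F0 and 83 B16F10 cells had their larger score within 0.05 of it. The summed S phase list stood at 1972 CPM in B16F0 and 2651 CPM in B16F10, and the G2 and M list at 3603 and 4920.3 CPM. The calls are made from the expression of these same genes, so no cycling rate is read from them.

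**Figure D3:**
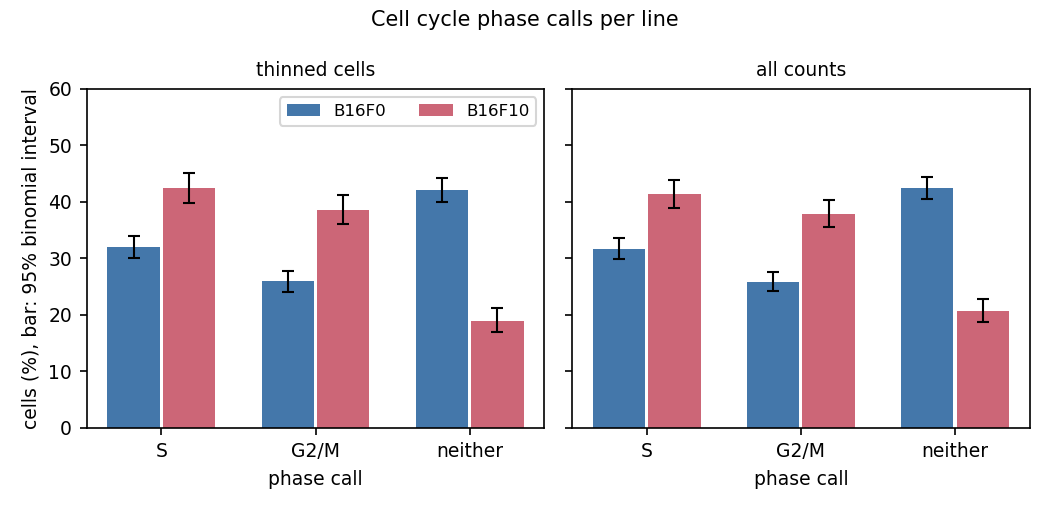
Share of cells (percent) called S, G2/M or neither in B16F0 and B16F10, on cells thinned to the same depth (left) and on all counts (right); bars are shares in 1 library per line and error bars exact 95% binomial intervals. The share called neither is 42.1% in B16F0 and 19.0% in B16F10 on thinned cells.

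Within cells of the same phase call, the interferon, lysosome, glycolysis and mesenchymal lists kept their direction. The interferon list had medians of -1.33 among S cells, -0.85 among G2/M cells and -1.04 among cells called neither, and the lysosome list had -0.40, -0.47 and -0.52. The glycolysis list had 0.66, 0.71 and 0.70, and the mesenchymal list 0.64, 0.87 and 0.71. The MHC class I list had -0.59, -0.19 and -0.58, so its difference was smallest among G2/M cells. The MAPK output list had 0.10 among S cells, 0.71 among G2/M cells and 0.44 among cells called neither. Hypoxia response genes had a median of 0.80 among cells called neither, above the value of 0.37 over all cells and outside its random range. Cdkn1a, lower in B16F10 over all cells, had a log2 ratio of 0.09 among cells called neither. There, 123 genes were at least 2-fold higher and 102 at least 2-fold lower in B16F10.

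The authors' deposited annotation also classes cells by Kdm5b, a histone demethylase gene linked to slowly cycling melanoma cells. Cells classed as Kdm5b high numbered 111 in B16F0 (4.30%, 3.55 to 5.15) and 121 in B16F10 (7.69%, 6.42 to 9.12), and Kdm5b itself stood at 9.60 and 14.3 CPM in the whole libraries (log2 ratio 0.57). S phase genes were lower in the Kdm5b high class, with a list median of -1.27 in B16F0 (38 of 39 members at least 1.5-fold lower) and -1.30 in B16F10 (40 of 42). G2 and M phase genes had -0.79 in B16F0 (29 of 48) and -0.53 in B16F10 (22 of 50). Pclaf had log2 ratios of -2.24 and -1.81 in B16F0 and B16F10, Top2a -2.05 and -1.61, and Rrm2 -1.79 and -1.52. Hypoxia response genes had medians of 0.42 in B16F0 (2 of 11 members at least 1.5-fold higher) and 0.77 in B16F10 (11 of 15), and Ero1l had log2 ratios of 0.64 and 1.58. The authors called 18.0% of Kdm5b high cells cycling in B16F0 (11.4 to 26.4), against 56.3% of Kdm5b low cells, and 36.4% (27.8 to 45.6) against 81.6% in B16F10. The Kdm5b comparison was not made within cycling or non-cycling cells. These list medians therefore cannot separate the Kdm5b class from the cycling state.

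The Kdm5b classes rest on few molecules. In B16F0, 63 of the 111 high cells held 2 or fewer Kdm5b UMIs, as did 56 high cells in B16F10, and 55 cells lay where the classes overlap on the natural log scale, as did 78 cells in B16F10. High cells were also shallower, with a median of 29878 UMIs against 35863 in B16F0 and 31174 against 35478 in B16F10. After thinning, 3.83% of B16F0 cells (3.07 to 4.72) and 6.43% of B16F10 cells (5.21 to 7.83) held at least 2 Kdm5b UMIs, where a Poisson spread around each line's mean would give 2.55% and 4.63%.

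Cells the authors called cycling and non-cycling also differed in genes outside the cell cycle lists. Hypoxia response genes, cycling over non-cycling, had medians of -0.18 in B16F0 (1 of 11 members at least 1.5-fold lower) and -0.58 in B16F10 (7 of 15). Lysosome genes had -0.20 and -0.25, with 1 of 23 and 1 of 22 members at least 1.5-fold lower. In B16F0 other lists were as low, such as interferon at -0.28, extracellular matrix at -0.26 and pigment at -0.21, while oxidative stress and iron had 0.04. The shift in B16F0 was therefore not particular to hypoxia or lysosome genes. In B16F10 the interferon, extracellular matrix and pigment lists had -0.32, -0.06 and -0.12, and cholesterol synthesis had 0.31. The p53 target list had a median of 0.02 in B16F0 and -0.45 in B16F10. Mxd4, a Myc antagonist, had log2 ratios of -1.16 in B16F0 and -2.22 in B16F10, and Hmox1 had -0.40 and -1.26. Kdm5b had -1.94 and -1.91, and Mitf had -0.31 and -0.38. The differences between the lines in these values were not tested.

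Of the authors' 5 clusters, C1, C2 and C5 held mostly cells of 1 line, and C3 and C4 held cells of both. Clusters C1 and C2 held 816 and 644 B16F0 cells but 7 and 4 B16F10 cells, and C5 held 13 B16F0 and 1045 B16F10 cells. With 1 library per line, such a cluster can be a library and not a cell state, so its size is not compared. C3 held 640 B16F0 and 306 B16F10 cells, of which 11.1% and 8.50% were called cycling, and C4 held 469 and 212 cells, of which 99.6% and 100% were called cycling. Within C3 the interferon list had a median of -0.78 and the mesenchymal list of 0.64, and within C4 they had -1.50 and 0.87. The glycolysis list had a median of 0.59 within C3 and -0.07 within C4. The B16F10 cells of C4 had a median mitochondrial share of 8.58%, against 4.87% for the B16F0 cells, and 249 genes were at least 2-fold higher and 283 at least 2-fold lower there.

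The variability of transcripts between cells was described within each line by the Fano factor of thinned counts, the variance divided by the mean. Its median was 1.10 over 8950 genes in B16F0 and 1.11 over 9094 genes in B16F10, where pure counting noise gives 1. Ccl5 had the largest value in B16F0, 102 at a mean of 1.43 UMIs per cell, and 59.1 in B16F10 at a mean of 0.291. The interferon-stimulated gene Ifit1 had 37.7 in B16F0 and 50.7 in B16F10, and Cxcl10 had 24.1 and 13.0. Malat1, Ftl1, Fth1 and Actb were also among the 10 genes with the largest values in both lines, 6 genes in all. At an equal relative spread the Fano factor grows with the mean, so it also ranks abundant transcripts high. Ftl1 had 58.2 in B16F0 at a mean of 473 UMIs per cell, a far smaller relative spread than that of Ccl5. Pmel, Ptgds and Ifit3 ranked in B16F0, with 25.3, 29.0 and 23.2, and Lgals3, Gapdh, Ppia and Chchd10 in B16F10, with 22.9, 20.8, 19.7 and 17.4. Some of these differ in level between the lines. Ptgds had means of 32.0 UMIs in B16F0 and 5.14 in B16F10, and Lgals3 had 1.92 and 11.3. A rank in 1 line therefore need not mean a larger relative spread there.

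Correlations across cells were taken between members of the same list, and none was taken between lists. The mean pairwise Pearson correlation of glycolysis genes was 0.184 in B16F0 and 0.334 in B16F10, and that of hypoxia response genes was 0.0570 and 0.166. Pigment genes had 0.277 in B16F0 and 0.184 in B16F10, lysosome genes 0.0849 and 0.0487, and interferon genes 0.193 and 0.151. Each of these values lay above all 1000 random lists matched on expression. Most of the other lists did so too in each line, for example the cytosolic ribosomal proteins at 0.317 in B16F0 and 0.320 in B16F10. Oxidative stress and iron genes had 0.0910 in B16F0, above all random lists, and 0.0302 in B16F10, inside the range of random lists. By Spearman correlation the hypoxia values were 0.0351 and 0.0931 and the interferon values 0.127 and 0.0848, and among cells called neither S nor G2/M the hypoxia values were 0.0848 and 0.316. The difference between the lines was not tested for any list.

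Gene ratios also differed by chromosome. Against a median log2 ratio of 0.12 over 5239 placed genes, the genes of chromosome 1 had a median of 0.39, those of chromosome 7 of 0.37, and those of chromosome 12 of 0.32. Chromosome 13 had a median of -0.29, chromosome 8 of -0.18 and chromosome 6 of -0.08. In all, 6 chromosomes lay above and 6 below the central 95% of random gene sets of the same size, and 8 lay inside. Unlike the random lists, these sets were not matched on expression. At a minimum of 100 CPM, chromosomes 2, 3 and 10 fell inside that range.

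**Figure D4:**
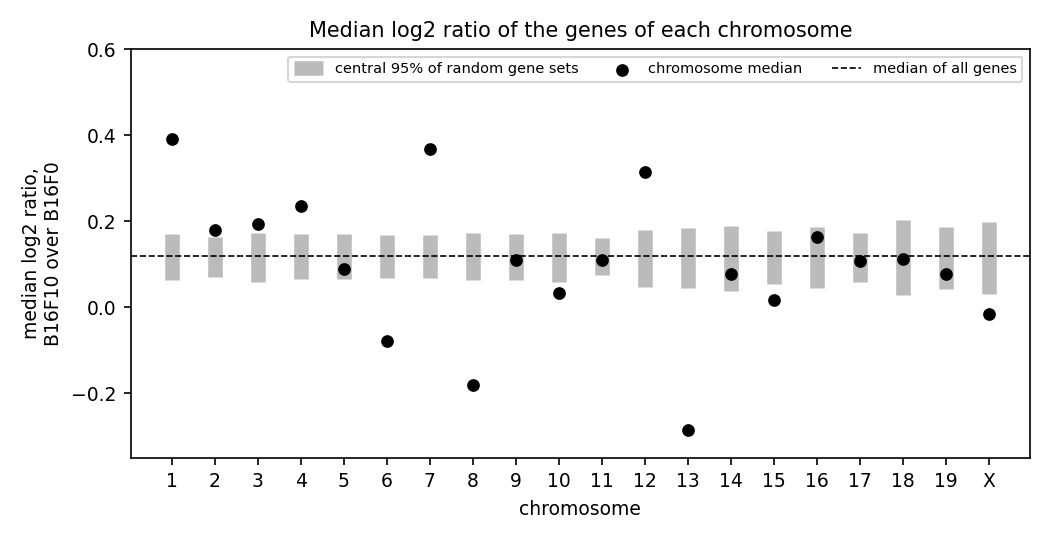
Median log2 ratio of CPM, B16F10 over B16F0, for the genes of each chromosome with at least 20 CPM in the higher library; points are medians, grey bars the central 95% of 10000 random gene sets and the dashed line the median of all genes. Chromosome 1 lies highest at 0.39 and chromosome 13 lowest at -0.29.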

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

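The tests on the cells grouped with the other line, and the test that left interferon-rich cells out of both lines, were chosen only after the result was seen.

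In the authors' first grouping, 121 B16F0 cells and 43 B16F10 cells were placed with the other line. On a scale over 178 genes where 0 is the rest of a cell's own line and 1 is the other line, the B16F0 cells had a median position of 0.281 and the B16F10 cells of 0.139, which argues against a wrong line label for either group as a whole. The B16F0 cells had a median mitochondrial share of 4.53%, below the 5.35% of their line, so damaged cells rich in mitochondrial transcripts are not a candidate there. The B16F10 cells had a median share of 11.2%, above the upper quartile of their line at 8.44%, and 26 of the 43 exceeded 10%. Cell damage is therefore a candidate, but B16F0 itself had a lower median share than the 6.72% of B16F10. Whether the share drove the placement was not tested. No biological explanation was tested for the B16F0 cells, in which Gadd45a had a log2 ratio of 2.10 and Rad54l of -1.98 over the rest of their line, and S phase genes had a list median of 0.62.

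The G2 and M phase genes had a list median of 0.54 between the lines. The median was 0.45 under TMM, but with 1 library per line TMM moves every gene by the same factor, the random lists included, so this could not test library scaling. Relative to the median of all genes, the list median was 0.43 under total scaling and 0.44 under TMM. Among cells the authors called cycling the median was 0.17, which is 30.8% of the value over all cells, between the bounds of 25% and 50% set for the test. Among non-cycling cells the median was 0.34, above its random range. A larger share of cycling cells in B16F10 and a higher level of these genes per cycling cell cannot be told apart, because the class is itself made from such genes. Whether the lines differ in growth rate stays open and untested.

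The interferon response genes had a list median of -1.13 between the lines. The test set before the result was seen left out the 5% of B16F0 cells with the highest share of these genes and moved the median to -0.39, 34.2% of its size, which met the condition set for a few strongly responding B16F0 cells as the cause. That test was badly built, because leaving out the highest cells of only B16F0 lowers that line whatever the cause, so the same share was then left out of both lines: the median was -1.14, with 9 of 10 genes still at least 1.5-fold lower, although Ifit1 moved from -0.99 to -3.22. This later test argues against a few cells as the whole cause, but it was chosen because of the first, and the 130 B16F0 and 79 B16F10 cells left out held 22.1% and 17.7% of the list's UMIs. A larger share of cycling cells and damaged cells were argued against by the medians within the cycling classes, of which the smaller in size was -1.01, and by -1.04 among cells with at most 8% mitochondrial UMIs. A lower interferon response in B16F10 cells may remain as a hypothesis, and with 1 library per line a difference between the cultures on the day of harvest is not excluded.

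The remaining results were marked because the Kdm5b high over Kdm5b low medians of a list had opposite signs in the lines, and for none of them was the difference between the lines tested. The MAPK output list had 0.11 in B16F0 and -0.19 in B16F10. The dedifferentiated or neural crest list had 0.18 in B16F0 and -0.10 in B16F10. The integrin list had -0.18 in B16F0 and 0.18 in B16F10. The secreted factor list had 0.14 in B16F0 and -0.12 in B16F10. All 8 medians lay inside the central 95% of their matched random lists.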

How the results depend on the processing

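The alternatives limited to the authors' cycling or non-cycling cells, to cells with at most 8% mitochondrial UMIs, and to cells not grouped with the other line were chosen only after the result was seen. Of the lists outside their random range, S phase alone changed sign under an alternative. Among lists inside their range, signs changed for heat shock, nuclear oxidative phosphorylation and p53 targets, given below, and for medians close to 0. Lists inside their range over all cells also left it elsewhere: heat shock at 0.38 with a minimum of 100 CPM, 0.43 with at most 8% mitochondrial UMIs and 0.39 among cycling cells, the pigment list at 0.22 among cycling cells, nuclear oxidative phosphorylation at -0.15 with at most 8% mitochondrial UMIs, and the unfolded protein response at -0.25 with 100 CPM. Hypoxia response did at 0.37 with at most 8% mitochondrial UMIs and with no CPM minimum, 0.38 with the mean of per-cell CPM and 0.36 with a total without mitochondrial and ribosomal protein genes. Of the ratios of named genes under the alternatives, 700 lay inside the counting interval of the value over all cells, 651 lay outside it, and 2, both of Cdkn1a, changed sign for a gene at least 1.5-fold changed. TMM and median-of-ratios factors move all genes alike and could not change the place of a list among random lists, apart from members crossing the CPM minimum. Of the lists outside their random range, MAPK output fell inside it with the mean of per-cell CPM (0.33), among cells with at most 8% mitochondrial UMIs (0.45), cells called neither (0.44), cycling (0.39) and non-cycling cells (0.41). So did the mitochondrially encoded list at 0.17 with at most 8% mitochondrial UMIs, though that cut is made on its own transcripts. The dedifferentiated or neural crest list also fell inside, at 0.40 among cells called neither and 0.41 among non-cycling cells. At 100 CPM the oxidative stress and iron list did at -0.11 and the S phase list at 0.27. Where a value moved or reversed, the cause was not tested unless given. Genes at least 2-fold higher numbered 123 among cells called neither S nor G2/M, 127 among the authors' non-cycling cells, 954 with no CPM minimum and 8 at a minimum of 100 CPM. Genes at least 2-fold lower numbered 1144 with no minimum and 26 at 100 CPM, and these minimums change the number of genes considered from 5296 to 14663 or 1535. The mesenchymal list had medians of 0.35 with a total without mitochondrial and ribosomal protein genes, 0.26 with no minimum and 0.12 at 100 CPM, all inside the random range, where its members differ in number.

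The S phase list reversed to -0.059 among cells called neither and to -0.027 among non-cycling cells, and had 0.048 among cycling cells. The G2 and M list had 0.29, 0.34 and 0.17 in the same sets, and these sets are chosen by such genes. The values of 0.29 and 0.34 lay above their random ranges, and 0.17 lay inside. Among cells called neither and among non-cycling cells, hypoxia genes had 0.80 and 0.72, nuclear oxidative phosphorylation genes 0.048 and 0.090, cholesterol genes -0.28 and -0.36, heat shock genes -0.26 and -0.30, and p53 targets 0.52 and 0.46. All of these left their random range among non-cycling cells, and hypoxia, cholesterol and p53 targets also did among cells called neither. In the same sets Cdkn1a reversed from -0.88 to 0.088 and 0.017. At 100 CPM the MHC class I list had -0.11 and the interferon list -0.80, and with no minimum the interferon list had -0.70. By the authors' calls, 45.4% of B16F0 and 21.9% of B16F10 cells were not cycling, and 54.6% and 78.1% were cycling, against 57.9% and 81.0% on thinned cells. At 100 CPM, relative to all genes, chromosome 7 had 0.19, chromosome 8 -0.41, chromosome 12 0.28 and chromosome X -0.22, and chromosomes 2, 3 and 10 fell inside their random range.

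Depth limits genes near 0.0318 CPM in B16F0 and 0.0529 CPM in B16F10. Another cluster resolution was not run, because the clusters are the authors'.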

Other observations

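Of the authors' 7 trajectory states, 1 and 7 held nearly all B16F10 cells, beside B16F0 cells. State 1 held 165 B16F0 and 1254 B16F10 cells, and state 7 held 454 and 319. States 2, 4 and 6 held 186, 547 and 569 B16F0 cells and 0 B16F10 cells, state 5 held 659 and 1, and state 3 held 2 and 0. The deposited pseudotime had a median of 8.14 in B16F0 and 10.9 in B16F10, and its root and settings are not given in the sources used here.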
